A study of Homo sapiens with 6 samples.

How the data were processed

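The series holds 6 RNA sequencing libraries of A375 cells, 3 transfected with an SLNCR plasmid and 3 with the empty plasmid. Per the labels' protocols, a lipid reagent delivered the plasmids, cells were selected with puromycin at 2 µg/mL for 48 h, ribosomal RNA was depleted, and fragments were read on an Illumina instrument from both ends at 150 bases. The deposited values are raw read counts per gene, as their whole numbers and unequal totals show. Per the submitters' processing notes, cutadapt, STAR and DESeq2 1.24.07 were used with build GRCh38. The role and order of these tools are not given there, and the read counter, the gene annotation and the strand setting are not given in the sources used here. Library preparation of this kind yields counts that depend on fragment GC content and length, and the GC content of genes was therefore followed through the comparisons.

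The table had 20238 rows, of which 18379 carried an Ensembl identifier and 2 a symbol (LINC00673 and HIF1A-AS2). The 1857 rows that name no gene held between 2.15% and 2.59% of the counts per library and stayed out of library sizes and tests. There were 22 runs of neighbouring rows with identical counts and a mean of at least 10. Only 1 row of each run was kept, which removed 63 rows with 0.611% to 0.745% of the counts. This left 18318 genes. GENCODE release 29 (GRCh38), whose genes matched the identifiers, gave coordinates, and 18344 identifiers were matched to a symbol. GC content and length were those of the longest transcript of a gene and were known for 99.9% of tested genes. The 7 genes with no GC value include LINC00673, HIF1A-AS2 and the histone genes H3C3 and H3C2. Coordinates of LINC00673 came from RefSeq (GRCh38.p14). Of the mitochondrially encoded transcripts 0 were among the rows used, so they were not analysed here.

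Totals per library in the table were between 9287450 and 10822083 counts. Between 12640 and 12900 genes had at least 10 counts in a library, so fold changes of genes near that level are imprecise. Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 1.62 to 5.52, so none was treated as a copy of another. The labels call the libraries biological replicates and do not say how the cultures were separated.

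The groups were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with robust dispersion, TMM factors, the default filterByExpr filter and no further covariate. Tests were two-sided with Benjamini-Hochberg adjustment over 12797 genes and a threshold of 0.05. Standard errors were derived from the log2 fold change and its F statistic. CPM values (counts scaled to a common library size) are TMM-scaled, and log2 values used a prior count of 2. Gene lists were tested with camera in limma 3.58.1 on log2 CPM, with an inter-gene correlation of 0.01. The list of E2F G1/S targets stood alone at an unadjusted p of 0.05. The other 27 lists with at least 5 tested members were adjusted together, and 3 of the 31 lists were too small to test. Intervals of list medians are 95% percentile intervals from 10000 bootstrap draws of genes, which are not replicates. The groups, tests, gene lists, named gene rule and most alternative analyses were fixed before the data were examined.

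The rule for named genes had 3 parts. The first was all measured SLNCR partners and E2F family members, and the second the 12 largest rises and 12 largest falls among changed genes with a mean count of at least 50 and no overlap between groups, for which 1097 and 915 genes qualified. The last was up to 4 members with the smallest adjusted p of each list described. HIF1A-AS2, HIF1A, H2BC7, RPLP1 and CAPN12 are named outside that rule, after their values were seen. Which lists are described member by member was also decided after the results were seen.

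The GC correction subtracted, in each library, a loess curve (span 0.5, second degree, symmetric family) of the deviation of log2 CPM from the gene mean against GC content, fitted on genes with a mean log2 value above 1. Genes with no GC value received the offset of the median GC content. The alternative was planned, and the settings of the curve were chosen with the data at hand. Other alternatives were size factors in the manner of DESeq2, upper quartile factors, no filter or a stricter filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out small RNAs, leaving out each library, other thresholds, camera with an estimated correlation, and fry. Added later were the GC correction without each library, the rows that name no gene, and camera on the quantile residuals of the counts. A planned test for E2F motifs in promoters was not run, since no genome sequence was used here.

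The edgeR fit and the GC correction were tested on simulated counts for this comparison, with 200 genes changed. With no GC trend (12678 genes run), 70% of changes of 0.5 and 95% of changes of 1 on the log2 scale were recovered, with 188 calls of which 23 were false. With the GC trend of these libraries added (12692 genes run), the uncorrected fit made 1219 calls, 1044 of them false, and the corrected fit made 191 calls, 18 of them false. The added trend was the same kind of curve that the correction fits, and genes were drawn independently. The simulation therefore shows only that the correction removes such a trend, and not how it performs on the real libraries. Of the 28 tested lists 26 are drawn, and 2 that were tested, neither of which passed camera, are not described here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.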

Results

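RNA was sequenced from A375 cells, an established human melanoma line, after transfection with a plasmid that expresses SLNCR or with the empty plasmid. SLNCR is a long non-coding RNA listed in RefSeq as LINC00673. There were 3 libraries per group, called biological replicates in the labels, and each was made from ribosomal RNA-depleted RNA collected after 48 h in 2 µg/mL puromycin, which kills cells that did not take up the plasmid. Total gene counts were 10498711, 9351940 and 9395845 in empty vector replicates 1, 2 and 3, and 10822083, 10722284 and 9287450 in SLNCR replicates 1, 2 and 3. After genes with few counts were set aside, 12797 genes were tested, and the biological coefficient of variation was 5.65%.

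The transfected RNA was the strongest change in the data. SLNCR (LINC00673) rose from 20.6 ± 1.04 CPM (TMM-scaled, SD, n = 3) with the empty vector to 215 ± 40.03 (SD, n = 3) with the SLNCR plasmid. This is 10.4-fold, or 3.38 on the log2 scale (SE 0.147, edgeR adjusted p = 3.11e-05). The raw counts were 195, 194 and 193 in the empty vector libraries and 1786, 2569 and 2040 in the SLNCR libraries. RefSeq places LINC00673 on chromosome 17 from 72403322 to 72592804 (GRCh38.p14), within the interval that GENCODE gives to the non-coding gene LINC00511 (72290091 to 72640472, minus strand). LINC00511 was counted apart, with a mean of 12.8 reads per library, and its log2 fold change was -0.41 (SE 0.335, edgeR adjusted p = 0.395). The counts do not separate plasmid from genomic transcripts of LINC00673. With a correction for gene GC content its log2 fold change was 3.38 (SE 0.201), and the edgeR adjusted p was 0.0539. The GC content of LINC00673 was not known, so this fit left its fold change as it was and changed its standard error.

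**Figure D1:**
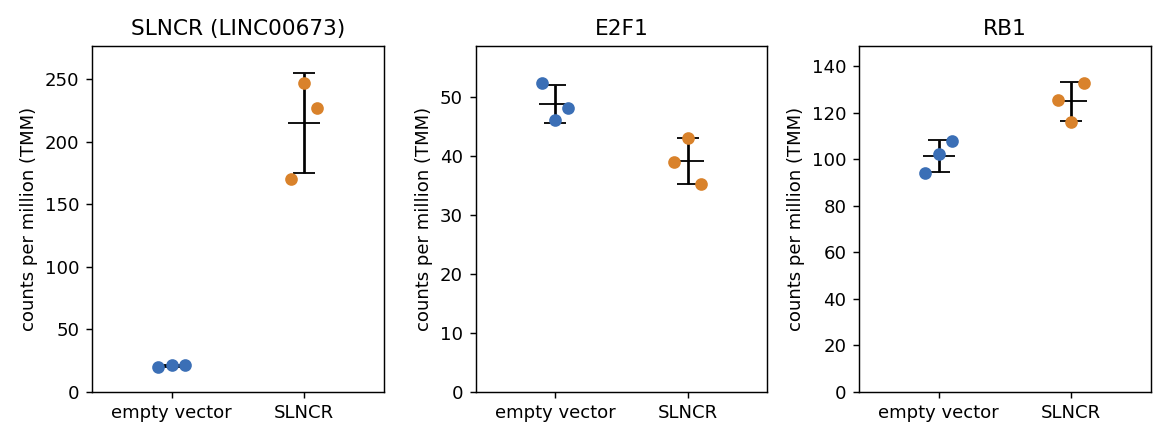
CPM (TMM-scaled, linear axes from 0) of SLNCR, E2F1 and RB1 in the 3 empty vector (blue) and 3 SLNCR (orange) libraries; points are libraries, and bars are the mean ± SD. SLNCR averages 20.6 and 215, and the E2F1 and RB1 groups do not overlap in these libraries.

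The first comparison asked which genes differ when SLNCR is overexpressed. Apart from SLNCR, changes were small. Among genes with a mean count of at least 50 whose groups did not overlap, the 11 largest rises after SLNCR were 1.47-fold to 1.53-fold. They were led by DNAJB9, a co-chaperone of the endoplasmic reticulum, with a log2 fold change of 0.62 (SE 0.105, edgeR adjusted p = 0.0137). The metalloreductase gene STEAP2 followed at 0.61 and the adaptor complex gene AP5M1 at 0.60. The sterol transfer protein gene STARD4 rose by 0.58, ACSM3 by 0.57, the DNA helicase gene HELB by 0.57 and the phosphatase gene PPM1H by 0.57. GNG2 and RTKN2 each rose by 0.56, as did the antisense RNA CERS6-AS1, and the non-coding RNA LINC02535 rose by 0.55. Among the 12 largest falls, MLYCD, which encodes malonyl-CoA decarboxylase, had a log2 fold change of -0.93 (SE 0.185, edgeR adjusted p = 0.0137). The homeobox gene HOXC9 followed at -0.85 and the pseudogene PI4KAP2 at -0.79. MORN1 and ODAD3 stood at -0.71, TSC22D1-AS1 at -0.70, and LIX1L-AS1 and CENPV at -0.69. The histone gene H2AC21, the MAPK scaffold gene KSR1, KYAT1 and PCED1B lay at -0.67, -0.67, -0.67 and -0.66.

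In all, 1131 genes were higher and 981 lower after SLNCR (2112 of 12797, edgeR adjusted p below 0.05), with a median absolute log2 fold change of 0.29. Only 13 of these genes changed by at least 1 on the log2 scale, 4 upward and 9 downward. The groups did not overlap for 2052 of the 2112 genes, which the test favours, and for 38.9% of all tested genes. For a single gene chance gives 10%. Genes that vary together can move the share of 1 split far from that, so the difference does not measure an excess. Higher and lower genes differed in base composition. The median GC content of the longest transcript was 38.9% among higher genes and 60.2% among lower genes, against 47.9% among all tested genes. Across genes, which are not independent replicates, the log2 fold change correlated with GC content at r = -0.637 (Spearman's rho = -0.692). In the tenth of genes lowest in GC content 486 rose and 1 fell, and in the tenth highest in GC content 1 rose and 398 fell. With a per-library correction for GC content, 91.9% of the 2112 genes kept their sign, at a median absolute log2 fold change of 0.10. After this correction, 2 of the 12797 genes passed and 1935 had an unadjusted edgeR p below 0.05. The 2 genes were the antisense RNA HIF1A-AS2, whose own GC content was not known and whose fold change the correction therefore left as it was, and the histone gene H2BC7. Both were chosen after their values were seen. The count of changed genes was 1, 2 and 1 without empty vector replicate 1, empty vector replicate 2 or SLNCR replicate 1, respectively, and 3366 without SLNCR replicate 2. LINC00673 passed in each of these fits without 1 library, where no GC correction was made.

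**Figure D2:**
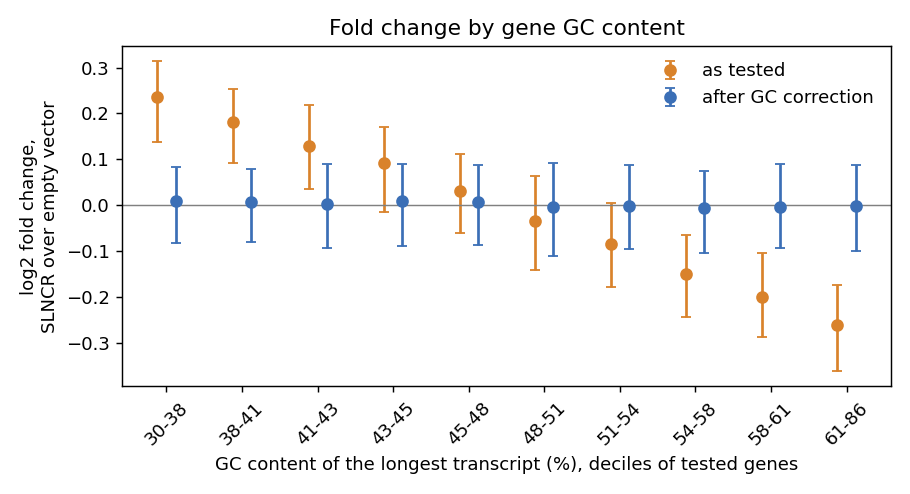
Log2 fold change (SLNCR over empty vector, y axis) of tested genes in deciles of transcript GC content (%, x axis); points are medians and bars run from the lower to the upper quartile, as tested (orange) and after the GC correction (blue). As tested, the medians run from 0.24 in the decile lowest in GC content to -0.26 in the highest.

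GC content also accompanied the individual genes with the largest changes. The 11 genes with the largest rises after SLNCR itself had a GC content from 34.2% to 49.0%, and the 12 with the largest falls from 44.3% to 62.9%. With the GC correction the rises lay between 0.32 and 0.59 and the falls between -0.79 and -0.43 on the log2 scale, and 0 of these 23 genes passed, with edgeR adjusted p from 0.0573 to 0.319. LINC00673 did not pass in that fit either (edgeR adjusted p = 0.0539), so not passing does not show that a change was lost. TSC22D1-AS1, at 44.3% GC, went from -0.70 to -0.77. PPM1H, at 49.0% GC, kept a log2 fold change of 0.59 (SE 0.149, edgeR adjusted p = 0.0903 after correction). CERS6-AS1, TSC22D1-AS1 and LIX1L-AS1 lie opposite other tested genes (CERS6 and NOSTRIN, TSC22D1, and LIX1L with RBM8A), and without a stated strand setting the reads of such partners cannot be told apart. DNAJB9 overlaps THAP5 and PNPLA8, HELB overlaps GRIP1, and HOXC9 overlaps HOXC6 in the annotation. AP5M1, STARD4, ACSM3, CENPV, ODAD3, KYAT1 and PCED1B also overlap tested genes. In all, 6 of the 11 rises and 7 of the 12 falls carry this uncertainty. PI4KAP2 is a pseudogene and H2AC21 a member of a multigene family, so their counts are uncertain where reads match several copies.

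Genes reported as partners or targets of SLNCR, and the E2F family itself, were examined whatever their result. E2F1, a transcription factor of cell cycle entry (chromosome 20, 33675683 to 33686404), fell from 48.8 ± 3.23 to 39.1 ± 3.89 CPM (SD, n = 3 each). Its log2 fold change was -0.32 (SE 0.0852, edgeR adjusted p = 0.0218), with no overlap between the groups. RB1, which encodes the pocket protein that restrains E2F factors (chromosome 13, 48303726 to 48599436), rose by 0.30 on the log2 scale (SE 0.0678, edgeR adjusted p = 0.0147). RB1 overlaps other tested genes on the opposite strand. The E2F1 transcript has a GC content of 62.5% and that of RB1 37.3%. With the GC correction the log2 fold changes were -0.08 (SE 0.0697, edgeR adjusted p = 0.588) and 0.09 (SE 0.0486, edgeR adjusted p = 0.413). E2F1 and RB1 each passed in 11 of 16 alternatives fixed beforehand. The other 11 of the 13 E2F family and pocket protein genes did not pass, among them E2F2 at -0.06, E2F3 at 0.08, E2F4 at -0.01, E2F5 at 0.19, E2F6 at 0.15, E2F7 at 0.14 and E2F8 at 0.10. TFDP1 and TFDP2, which encode dimerization partners, stood at -0.04 and -0.01, and RBL1 and RBL2 at 0.17 and 0.11. As a list, the family had camera adjusted p = 0.395.

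Among the genes reported as SLNCR partners or targets, E2F1 fell, while EGR1, CDKN1A, SOX9, TFAP2A and PXN did not pass. EGR1, an immediate early gene, had a log2 fold change of -0.19 (SE 0.108, edgeR adjusted p = 0.219). CDKN1A, which encodes the cell cycle inhibitor p21, stood at 0.01, SOX9 at -0.13, TFAP2A at -0.23 and PXN at -0.07. With the GC correction CDKN1A stood at 0.18 (SE 0.0456, edgeR adjusted p = 0.0886). EGR1 then stood at -0.06, SOX9 at -0.07, TFAP2A at -0.20 and PXN at 0.14, and again none passed. The sign for CDKN1A, E2F4, TFDP2, PXN, E2F2 and E2F5 turned under at least 1 alternative, and upper quartile scaling put CDKN1A at -0.0040. MMP9 was counted at 1, 0 and 2 reads in the empty vector libraries and 0, 1 and 1 in the SLNCR libraries, too few for a test, so a difference was not detectable at this depth. POU4F1 was not analysed here.

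The second comparison asked whether target genes of E2F factors moved, since the study concerns SLNCR and E2F1. The replication genes that E2F factors switch on at the entry into S phase did not shift as a group. Of 72 tested G1/S targets, 7 were higher, 9 were lower and 56 did not pass, and adjusted over the list alone 7 were higher and 10 lower. Their median log2 fold change was -0.01 (95% bootstrap interval over genes -0.07 to 0.08), and camera gave p = 0.932, where in an exact permutation of the groups 10 of 10 splits gave a p as low. The camera direction was up, while the median and the mean lay below 0. With an estimated correlation camera gave p = 0.942. RAD51AP1, a recombination gene, rose by 0.34 (SE 0.0840, edgeR adjusted p = 0.0174). The licensing factor gene CDT1 and the DNA ligase gene LIG1 both fell by 0.38 on the log2 scale (edgeR adjusted p = 0.0181 and 0.0209). RAD51AP1 has a GC content of 36.1%, CDT1 64.9% and LIG1 56.4%, and after GC correction the list median was -0.01 and camera again did not pass. The mean of the list in single libraries stayed between -0.05 and 0.01 relative to the empty vector mean. Of 16 tested apoptosis targets of E2F1, 0 passed in either direction with edgeR (camera adjusted p = 0.773; median 0.05, mean -0.06).

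A further 27 gene lists, fixed before the data were examined, were tested together, and 3 were lower after SLNCR with camera at its preset correlation. Replication-dependent histone genes, which supply chromatin during DNA synthesis, were lower by a median of -0.36 on the log2 scale (95% bootstrap interval -0.42 to -0.30). Of 49 tested members 23 fell, 0 rose and 26 did not pass, and adjusted over the list alone 37 fell (camera adjusted p = 1.58e-10, but 0.688 with an estimated correlation, 0.796 between members). H3C4 fell by 0.35, H2AC8 by 0.42, H2BC18 by 0.36 and H2BC15 by 0.40 on the log2 scale, each with edgeR adjusted p = 0.0137. The list mean was -0.33, -0.16 and -0.65 in SLNCR replicates 1, 2 and 3, and 0.14, -0.04 and -0.11 in empty vector replicates 1, 2 and 3. In the same SLNCR libraries the mean of abundant small or nuclear non-coding RNAs, a list read for RNA quality, was -0.21, 0.01 and -0.33 (-0.03, 0.02 and 0.01 in empty vector replicates 1, 2 and 3), and that of keratinocyte and epithelial markers -0.15, -0.12 and -0.32. Without SLNCR replicate 3 the histone median was -0.25. The median GC content of the list was 56.2%, and after the GC correction its median was -0.29 (camera adjusted p = 3.16e-11, but 0.877 with an estimated correlation), with 1 member, H2BC7, passing. The GC content of 2 members, H3C3 and H3C2, was not known, and the corrected median of the other 47 was -0.27. H2BC7, whose longest transcript has 42.7% GC, went from -0.25 to -0.36 with the correction. Histone genes form a multigene family, so reads of near-identical copies are uncertain between members.

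Genes for cytosolic ribosomal proteins were also lower, by a median of -0.14 (95% bootstrap interval -0.18 to -0.09, camera adjusted p = 1.41e-05, but 0.688 with an estimated correlation). Without SLNCR replicate 3 the median was -0.08. Of 75 tested members 14 fell, 1 rose and 60 did not pass, and adjusted over the list alone 15 fell and 1 rose. RPS28 fell by 0.36, RPS15 by 0.30 and RPS3 by 0.25 on the log2 scale, while RPS3A rose by 0.26. After GC correction the list median was -0.13 (-0.16 to -0.11, camera adjusted p = 5.47e-08, but 0.877 with an estimated correlation). With that correction 92 other protein-coding genes with transcripts of up to 800 bases, histones left out, had a median of -0.08. A lower yield of short transcripts was not tested for the ribosomal list. Many of these genes have processed pseudogenes that can share reads. The list mean was -0.14, -0.07 and -0.31 in SLNCR replicates 1, 2 and 3, beside -0.21, 0.01 and -0.33 for the RNA quality list and -0.15, -0.12 and -0.32 for keratinocyte and epithelial markers.

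Immediate early and AP-1 genes, which encode quickly induced transcription factors, were lower by a median of -0.21 (95% bootstrap interval -0.25 to -0.15, camera adjusted p = 7.28e-04, but 0.688 with an estimated correlation). Of 25 tested members 10 fell, 0 rose and 15 did not pass, and adjusted over the list alone 12 fell. FOSB fell by 0.43, IER2 by 0.37, IER5 by 0.36 and FOSL2 by 0.24 on the log2 scale. The median GC content of the list was 55.4%, and with the GC correction its median was -0.01 and the list no longer passed (camera adjusted p = 0.393). Without SLNCR replicate 3 its median was -0.16. The list mean was -0.17, -0.13 and -0.25 in SLNCR replicates 1, 2 and 3, beside the -0.21, 0.01 and -0.33 of the RNA quality list and the -0.15, -0.12 and -0.32 of the keratinocyte and epithelial markers.

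**Figure D3:**
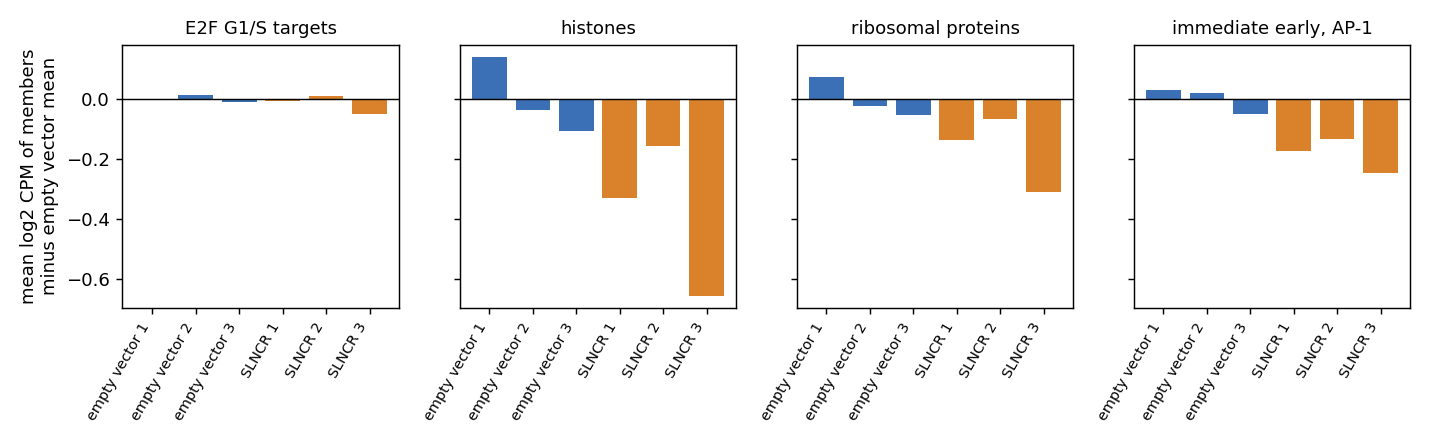
Mean log2 CPM of list members minus their empty vector mean (y axis, log2 units), 1 bar per library, for 4 gene lists; blue bars are empty vector and orange bars SLNCR libraries. The histone bars reach -0.65 in SLNCR replicate 3 and -0.16 in SLNCR replicate 2, and the E2F target bars stay between -0.05 and 0.01.

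The other 24 lists did not pass camera at an adjusted p of 0.05. For mitotic genes of the DREAM and FOXM1 programme, 13 of 57 rose and 6 fell (camera adjusted p = 0.129), and adjusted over the list alone 19 rose and 6 fell. SGO2 rose by 0.39, NUF2 by 0.33, KIF20B by 0.27 and SMC4 by 0.24, all with a GC content below 39%, and the list median went from 0.06 to -0.01 with the GC correction. Among 35 targets of p53, 6 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.55). KITLG rose by 0.52, CCNG1 by 0.45 and the death receptor gene FAS by 0.29, and FDXR fell by 0.45. Of 48 targets of MYC, 3 rose and 7 fell (6 and 10 adjusted over the list alone; camera adjusted p = 0.177), with DDX18 at 0.25, NOP58 at 0.24, FARSA at -0.40 and SRM at -0.21. SRM stood at 0.05 after the GC correction.

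No list of melanoma cell states passed camera. Of 24 melanocyte differentiation genes 2 rose, 1 fell and 21 did not pass (camera adjusted p = 0.773), and 0 passed in edgeR adjusted over the list alone. MYO5A, which moves pigment granules, stood at 0.23, SLC24A5 at 0.52 and SLC7A5 at -0.14, and with the GC correction SLC7A5 stood at 0.08. Of 43 genes of the dedifferentiated and invasive state 4 rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.827). The integrin genes ITGAV and ITGA2 rose by 0.28 and 0.25, while the collagen gene COL6A1 fell by 0.27 and VIM by 0.17. Among 18 matrix metalloproteinases and inhibitors, ADAM10 passed at 0.21 and 17 did not (0 adjusted over the list alone; camera adjusted p = 0.395). Of 22 genes of MAPK pathway output 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.827).

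Stress lists were likewise split in direction. Of 38 genes of the unfolded protein response and ATF4 4 rose and 5 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.395), with the chaperone gene HSP90B1 at 0.16 and STC2 at -0.27. Of 20 heat shock genes 2 rose and 2 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.982). In a list of genes from the wider chromosome region of SLNCR, MAP2K6 rose by 0.42 (SE 0.111, edgeR adjusted p = 0.0211). The other 10 of 11 tested members did not pass (1 adjusted over the list alone, camera adjusted p = 0.395). MAP2K6 (chromosome 17, 69414698 to 69553861) is not adjacent to LINC00673, which starts at 72403322, and SOX9 (72121020 to 72126420) lies between them. After the GC correction MAP2K6 stood at 0.23 (edgeR adjusted p = 0.351).

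Markers of other cell types and signs of RNA quality were read in the same libraries. Of 6 tested keratinocyte and epithelial markers 0 rose and 3 fell (4 fell adjusted over the list alone; camera adjusted p = 0.177). KRT18 fell by 0.29, KRT8 by 0.31 and SFN by 0.43 on the log2 scale, and after correction for GC they stood at -0.15, -0.16 and -0.19. KRT8 and KRT18 overlap on opposite strands. In edgeR, 0 of 6 fibroblast markers passed (camera adjusted p = 0.982), and 0 of 4 tested immune and 0 of 2 tested endothelial markers did. Of 10 tested abundant small or nuclear non-coding RNAs 0 passed with edgeR (camera adjusted p = 0.395), and their mean was -0.21, 0.01 and -0.33 in SLNCR replicates 1, 2 and 3. The share of counts taken by RN7SK lay between 1.55% and 1.70% in the 6 libraries.

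**Figure D4:**
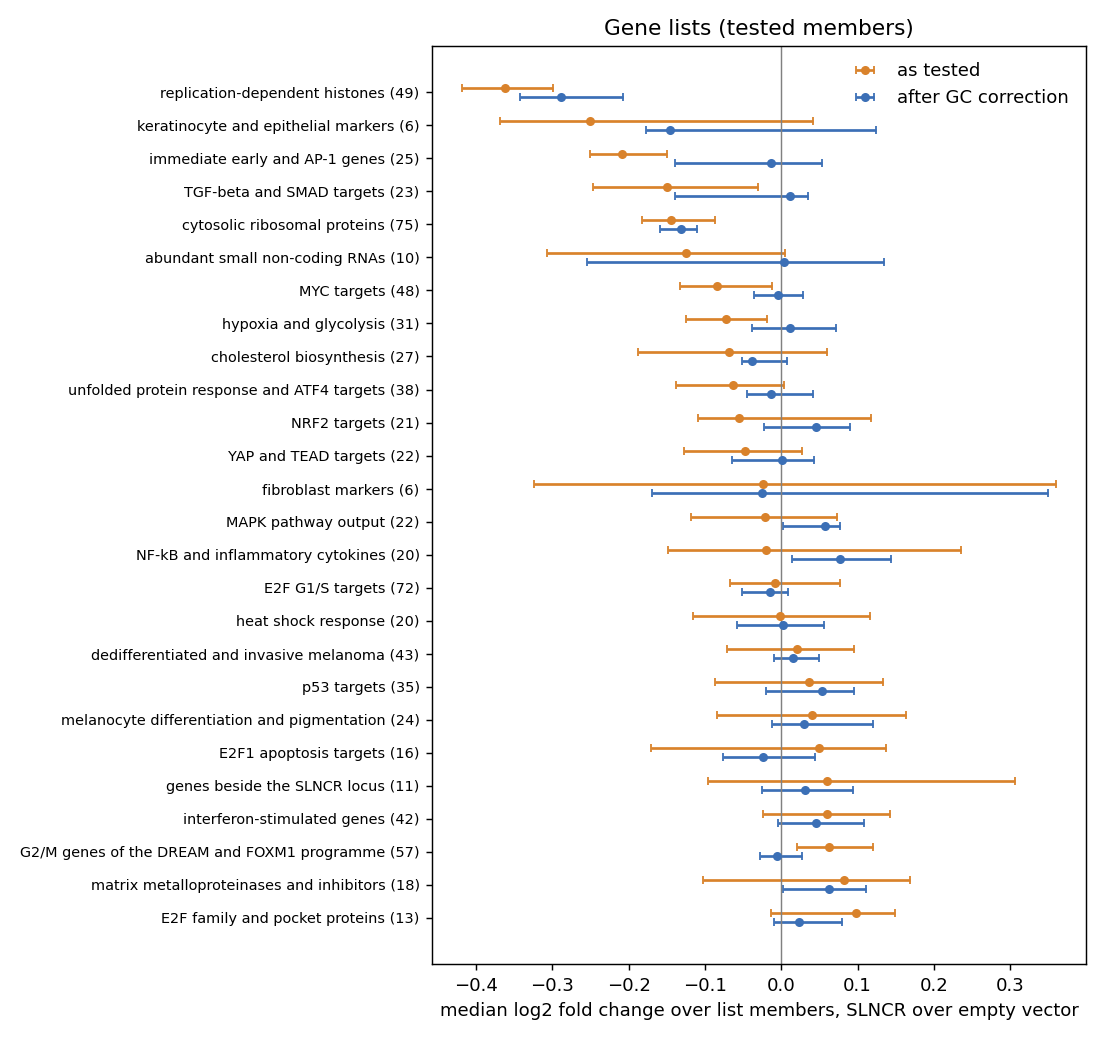
Median log2 fold change (x axis, SLNCR over empty vector) of 26 gene lists with at least 5 tested members, whose number is given in parentheses; bars are 95% bootstrap intervals over genes, as tested (orange) and after GC correction (blue). The histone list lies at -0.36 and at -0.29 with the correction, and the E2F target list at -0.01 in both.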

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

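The test of GC bias between single libraries and that of the S phase share were chosen after the results they concern were seen, and the others below were set out before their results were seen. The tests of the immediate early genes were set aside once results were known and later restored unchanged. Conditions on spread were added to the tests of short transcripts and of immediate early genes without SLNCR replicate 3 after their values were seen, and altered no outcome.

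The rows that name no gene were set apart from the comparisons. Tested together with the named genes, 33 of 819 such rows were higher in the SLNCR libraries than in the empty vector libraries, and 33 were lower (edgeR adjusted p below 0.05). What these rows count is not given in the sources used here. The 66 make up 8.06% of these rows, less than the 16.5% of named genes, so they do not stand out by number and are given because they were left out of the comparisons.

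The 6 libraries can be split 3 against 3 in 10 ways, which is too few for a share under 0.05. The real split called 2112 genes, more than the other 9 splits, of which the highest called 0 with edgeR, so 1 split gave as many. For the E2F G1/S list, all 10 splits gave a camera p at or below the real value of 0.932, the lowest of the others being 0.0832. For the other lists, 4 splits called at least the real 3 lists, and the highest other split called 5.

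Fold changes fell with gene GC content. Transcript length does not account for this, since within tertiles of length the weakest correlation of the fold change with GC content was r = -0.534. Nor does SLNCR replicate 3 alone, since r was -0.548 without it. A GC bias that differs between single libraries may account for it, since libraries of the same group also differed from each other along GC content, with an absolute r of up to 0.427. A split that mixed the groups reached an absolute r of 0.544, against 0.637 for the real split. That split kept most libraries of each group on one side, so a group difference would raise its r as well. Empty vector replicate 3 and SLNCR replicate 2, the closest pair between groups, differed less along GC content (0.299) than SLNCR replicates 2 and 3 (0.427), the farthest pair within a group. Every other pair between groups differed more than any pair within a group, up to 0.647. Still, all 3 empty vector libraries deviated one way (r = 0.598, 0.496 and 0.267) and all 3 SLNCR libraries the other way (-0.459, -0.199 and -0.589). An effect of SLNCR that follows GC content therefore stays open, untested.

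Replication-dependent histone genes were lower. With GC content taken from the longest transcript, the list stayed lower after the correction for the GC trend. The list median was -0.288 after the correction (95% bootstrap interval -0.342 to -0.207). It was -0.272 (-0.342 to -0.207) for the 47 members with a known GC content, a value added after the result was seen. The correction deepened the fall of H2BC7 (42.7% GC, -0.25 to -0.36) and H2BC15 (39.5%, -0.40 to -0.57). Among GC-rich members it left H2AC14 (62.5%) at -0.44, H2AC12 (61.8%) at -0.34, H3C4 (62.3%) at -0.12, H3C12 (62.45%) at -0.02 and H4C12 (64.1%) at 0.36. Whether the reads came from those longest transcripts was not tested, and this test and the next rest on that measure. A GC content set too low for some members would leave such a remainder, so the test cannot exclude the GC trend. The 98 other protein-coding genes with transcripts of up to 800 bases fell less, with a median of -0.0837 after the correction (-0.127 to -0.0196). This lay above the histones by 0.205, with a bootstrap interval over genes that excludes 0. Those genes were not matched in length to the histones, whose median transcript length was 509 bases. The interval does not measure variation between libraries, so a lower yield of short transcripts is not excluded. A smaller share of cells in S phase could be the source but was not settled by the E2F G1/S list, whose median was -0.00763 while its members went both ways and need not move as far as histones. The camera call is lost with an estimated correlation, so variation between libraries that histone genes share stays open as well. The histone means ran in the order of the libraries' deviations along GC content, in the empty vector libraries (0.598, 0.496 and 0.267) and in the SLNCR libraries (-0.459, -0.199 and -0.589). The means of the ribosomal protein list did the same. RNA quality also stays open, and its list shared the order of the histones in the SLNCR libraries but not in the empty vector libraries. The median GC content of the RNA quality list was 60.4%, and its median went from -0.13 to 0.0041 with the GC correction. Its order in the SLNCR libraries therefore cannot be told apart from the GC trend.

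Immediate early and AP-1 genes were lower. Without SLNCR replicate 3 their median was -0.162 (95% bootstrap interval -0.252 to -0.116), which argues against that library alone. The GC trend across all genes may be enough, since after the correction the list median was -0.0140 (95% bootstrap interval -0.139 to 0.0528). An effect of SLNCR on these genes within the trend stays open, untested.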

How the results depend on the processing

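The GC correction combined with leaving out a library, the lines that name no gene and camera on quantile residuals were chosen after the data were seen. The 2112 changed genes became 2095 with DESeq2-style factors, 2085 with upper quartile factors, 2904 with no filter, 2139 with limma-voom, 2130 without small RNAs and SLNCR and 1641 with DESeq2, which shared 1590 of them. The stricter filter removed no tested gene and shows nothing. The promoter motif test and its variants were not run, for want of a genome sequence. Adding the table lines that name no gene gave 2138. The count was 3642 at an adjusted p below 0.1, and 13 with a log2 fold change of 1 or more. With the GC correction it was 2 (159 at an adjusted p below 0.1). Leaving out 1 library gave 1 to 3366 genes (1 without empty vector replicate 1, 2 without empty vector replicate 2, 1884 without empty vector replicate 3, 1 without SLNCR replicate 1, 3366 without SLNCR replicate 2, 1517 without SLNCR replicate 3). The call left in those fits was LINC00673, with RPLP1 as the other without empty vector replicate 2. Unadjusted p-values below 0.05 numbered 2957, 3473 and 3663 in the 3 fits with 1 or 2 calls. With the GC correction as well, the range was 0 to 668, with 0, 1, 4, 2, 668 and 101 genes in the same order. The 0 came from edgeR, with 1212 genes at an unadjusted p below 0.05, the 1 was RPLP1, the 4 were CAPN12, H2BC15, H2BC7 and HIF1A-AS2, and the 2 were HIF1A-AS2 and LINC00673. The cause of the losses was not tested.

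With the replicate number as a block, 3523 genes were called, and with the GC correction and the block 407. Same-numbered libraries correlated at 0.159, -0.0189 and 0.370 in their deviations, not all above 0.1, and not every library correlated best with its own number, so the numbers were not taken to pair the libraries. The camera p of the E2F list was 0.909 with the block and 0.107 with the block and the GC correction, both in the opposite direction, and the other lists called numbered 3 and 2.

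The E2F list did not pass in any alternative. Its direction turned, never past the threshold, with limma-voom (p = 0.918), the GC correction (0.147), and camera on quantile residuals with a preset (0.830) or an estimated correlation (0.849). Leaving out 1 library gave p from 0.644 to 0.955, and the direction also turned without empty vector replicate 1 (0.917) and without SLNCR replicate 2 (0.811). The other lists called numbered 3 in every fit without 1 library, 2 with the GC correction, which lost the immediate early list, and 0 with an estimated correlation (of log2 values or quantile residuals) or with fry, where the camera tests on log2 values held 3 at the preset correlation.

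Of 80 named genes that passed, 2 still passed with the GC correction, HIF1A-AS2 and H2BC7, which had been named because they did, so 0 of the genes named by the rule passed. Of the others 3 changed sign, namely TNFAIP2 (0.0239), SRM (0.0514) and SLC7A5 (0.0774), at 0.0238, 0.0512 and 0.0769 with the block. Among genes that had not passed, PXN (0.140, with the block 0.138), E2F2 (0.101, 0.0974), E2F4 (0.186, 0.182, past the threshold with the block) and E2F5 (-0.0095, -0.0089) turned. CDKN1A turned with upper quartile factors (-0.00398), and E2F4 (0.00561) and TFDP2 (0.00214) with no filter. Without 1 library, values ran from -0.0343 to 0.0421 for CDKN1A, -0.0489 to 0.0270 for TFDP2, -0.141 to 0.00966 for E2F2 and -0.0718 to 0.0358 for E2F4. LINC00673 passed in 14 of 15 alternatives fixed beforehand, with log2 fold changes of 3.26 to 3.52 and a highest adjusted p of 0.0539. It did not pass in any of the 3 fits with the GC correction and without an empty vector library. At 9287450 to 10822083 counts per library, genes with few reads such as MMP9 could not be tested.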

Other observations

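The gene lists of this part held both higher and lower members, and none passed camera. Of 20 tested NF-kB and inflammatory cytokine genes 3 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.773; median -0.02, mean 0.08). The chemokine gene CXCL8 rose by 0.40, the prostaglandin synthase gene PTGS2 by 0.51 and BIRC3 by 0.53, and TNFAIP2 fell by 0.21 on the log2 scale. These 3 genes that rose have a GC content of 33.4%, 36.9% and 34.8%, and TNFAIP2 one of 62.0%. Of 42 interferon-stimulated genes 4 rose and 1 fell (0 adjusted over the list alone; camera adjusted p = 0.395). Of 31 genes of hypoxia and glycolysis 3 rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.395). The histone demethylase gene KDM3A and the oxidoreductase gene ERO1A rose by 0.33 and 0.31, and the phosphofructokinase genes PFKL and PFKFB3 fell by 0.38 and 0.34 on the log2 scale. Of 27 genes of cholesterol biosynthesis 4 rose and 5 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.395), with SC5D at 0.37, MVD at -0.59 and the fatty acid synthase gene FASN at -0.32. With the GC correction 0 of the genes named in this paragraph passed in edgeR.

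Of 21 targets of NRF2 2 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.827), of 22 targets of YAP and TEAD 2 rose and 2 fell (3 and 3; camera adjusted p = 0.649), and of 23 targets of TGF-beta 1 rose and 3 fell (the same numbers; camera adjusted p = 0.112).

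HIF1A-AS2, an antisense RNA, was singled out after its values were seen, as the gene that rose past the threshold with the GC correction. It went from 88.4 ± 5.03 to 128 ± 13.8 CPM (SD, n = 3 each), higher in 3 of 3 SLNCR libraries than in any empty vector library. Its log2 fold change was 0.53 (SE 0.0750, edgeR adjusted p = 0.00989), and 0.53 (SE 0.0675, edgeR adjusted p = 0.00599) with the correction, for which its GC content was not known. It passed in 13 of 16 alternatives fixed beforehand, with edgeR or other adjusted p up to 0.106. With the GC correction and a library left out, it did not pass without empty vector replicate 1 or without empty vector replicate 2. RefSeq places it on chromosome 14 from 61747039 to 61749089 (GRCh38.p14), over the end of HIF1A (61695513 to 61748259, plus strand). HIF1A itself rose by 0.24 (SE 0.0605, edgeR adjusted p = 0.0181), and stood at 0.01 with the correction. Without a stated strand setting, reads of this pair cannot be told apart.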
